A study of Mus musculus with 14 samples.

How the data were processed

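Gene expression was measured by sequencing polyadenylated RNA (NEBNext Ultra II directional kit, paired reads of 150 bases, per the labels' protocols) from layer II/III tissue microdissected from mouse cortex at postnatal day 5. There were 14 libraries in 4 groups: progenitor control and progenitor labelled mutant (n = 4 each), and postmitotic control and postmitotic labelled mutant (n = 3 each), as the labels give them.

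The authors deposited a table of counts for each experiment: whole-number read counts per gene symbol, not normalised. Per the submitters' processing notes, HISAT2, featureCounts and DESeq2 were used with build mm10; their versions, the annotation and the strand setting are not given in the sources used here. The tables hold 25229 and 55353 symbols, of which 24690 are in both. No test compared levels between them, and CPM of both given side by side come from separate tables. The authors also deposited a table of DESeq2 results for each experiment, per the file headers, with log2 fold changes, p-values and adjusted p-values. In these tables missing values had been replaced by 0, also inside gene symbols, so 397 and 420 symbols were restored, and 9215 and 39786 adjusted p-values of 0 that stand for missing ones were not counted as calls. The mean counts in the authors' deposited progenitor table matched those of all 8 libraries within 0.1% for 100% of 15286 genes with a mean above 10. Those in the postmitotic one matched controls 1 and 2 with mutants 1 and 2 for 100% of 17653 genes, and no other choice of libraries for more than 2.80%. The files held 0 columns of other samples. Counts of the mitochondrially encoded genes were not analysed here; pseudogenes resembling them took 1.34% to 1.69% of the postmitotic counts, and Rn45s took 0.199% to 0.364% of the progenitor counts.

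Library totals ranged from 22677019 to 29497595 counts in the progenitor and from 21605777 to 25891416 counts in the postmitotic experiment, and 18394 to 18749 and 26643 to 27443 genes had a count. Replicates of a group differed by far more than sampling noise (chi-square per degree of freedom 6.31 to 19.6), so none was counted as a duplicate. The common biological coefficient of variation was 0.110 in the progenitor and 0.112 in the postmitotic experiment.

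Each experiment was tested alone with edgeR 4.0.16 in R 4.3.3: genes kept by filterByExpr, TMM factors, a robust quasi-likelihood fit (glmQLFit) and its F test (glmQLFTest), with Benjamini-Hochberg adjustment and a gene called at an adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of F, and 95% bounds use the t distribution with the degrees of freedom of that test. Log2 fold changes are libraries labelled mutant over control, and CPM use the TMM-scaled library sizes. The difference between the experiments was the interaction of experiment and label in 1 fit of all 14 libraries over the shared symbols. Shared calls were tested per direction with a two-sided Fisher's exact test. Lhx2 also had an exact permutation test of its CPM.

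Before the data were examined, 31 gene lists were fixed. They cover Wnt and Notch signalling, neuronal identity, dendrites, axons, synapses and channels, stress and metabolism, and markers of other cell types, and each is named where its result is given. Lists with at least 5 measured members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with the correlation estimated from the data. Member counts are given over all tested genes and adjusted over the list alone. The rule for naming genes was also fixed then. It takes Lhx2, up to 10 called genes per direction with the largest change, no overlap of CPM between groups, at least 5 CPM in the higher group and no predicted-gene name. It adds up to 3 members per list with the smallest p, the 10 genes with the smallest p for the difference, the 10 shared genes with the smallest larger p, and Sox11, Neurog2, Cux1, Cux2, Axin2 and Lef1. Some results that this rule names are not reported here. Neurod6 and the genes said to be so were chosen after their values were seen.

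Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, other scaling factors and filters, no robust step, another threshold, a test against a fold of 1.5, the replicate number as a block, 1 fit of all libraries, other list tests, and leaving out each library in turn. Leaving out X and Y genes or mitochondria-like pseudogenes, Y-linked CPM as a covariate, removal of a trend on exon length, counts thinned to the lowest library total, postmitotic libraries 1 and 2 of each group alone, shared genes with each library left out, and camera on the difference were added after seeing the data. Positions are those of GENCODE M21 on GRCm38/mm10, matched by symbol for 98.3% of progenitor and 98.5% of postmitotic symbols.

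The procedure was tested on simulated counts with 200 changed genes and a planted list of 40 more, raised by 0.5 on the log2 scale. In the simulated progenitor comparison (15155 genes) 62.7%, 91.0% and 97.0% of genes changed by 1.5-fold, 2-fold and 4-fold were called, with 13 of 14916 unchanged genes. In the simulated postmitotic comparison (17502 genes) these shares were 49.3%, 70.1% and 97.0%, with 15 of 17265, and in the simulated difference (15449 genes) 31.3%, 71.6% and 84.8%, with 8 of 15211. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.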

Results

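RNA from layer II/III of the cerebral cortex of mice at postnatal day 5 was sequenced in 14 libraries that fall into 4 groups. Lhx2 is a LIM-homeodomain transcription factor of cortical progenitors and upper-layer neurons. The series asks how its loss acts on the dendrites of these neurons when the gene is removed in progenitors or only after the last division. In the progenitor experiment, Lhx2lox/lox cortices were electroporated in utero at E15.5 with an EGFP plasmid (control, n = 4) or with a Cre-EGFP plasmid (libraries labelled mutant, n = 4). In the postmitotic experiment, an EGFP plasmid was electroporated into Lhx2lox/lox cortices (control, n = 3) or into cortices that also carried NexCre, a Cre allele at the Neurod6 locus that acts in young excitatory neurons (libraries labelled mutant, n = 3). Total counts were 24947089, 26618704, 26056732 and 29497595 in progenitor controls 1 to 4, and 22677019, 23312959, 24002981 and 22859322 in progenitor libraries 1 to 4 labelled mutant. They were 24811760, 25150658 and 21605777 in postmitotic controls 1 to 3, and 25025871, 25891416 and 24078099 in postmitotic libraries 1 to 3 labelled mutant. Every progenitor control was thus deeper than every progenitor library labelled mutant. Counts of Y-linked genes exceeded 1 CPM in 0 of 4 progenitor controls and in 3 of 4 progenitor libraries labelled mutant (2, 3 and 4). They did so in 2 of 3 postmitotic controls and in 1 of 3 postmitotic libraries labelled mutant. Progenitor library 3 labelled mutant had both Y-linked counts (99.8 CPM) and Xist, the noncoding RNA of the inactive X chromosome (557 CPM). The other 5 libraries over 1 CPM of Y-linked counts had at most 7.98 CPM of Xist. Nothing in the labels says that each library came from a separate animal, so the p-values cover the spread between these libraries, part of which may be technical.

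Lhx2 itself (chromosome 2, 38339281 to 38369733, plus strand, GRCm38/mm10) was not lower in either set of libraries labelled mutant. In the progenitor experiment it had 127 ± 9.10 CPM in controls and 130 ± 11.4 CPM in libraries labelled mutant (SD, n = 4 each), a log2 fold change of 0.02 ± 0.07 (SE). An exact two-sided permutation test of these CPM gave p = 0.743. In the postmitotic experiment it had 147 ± 3.48 CPM in controls and 179 ± 7.41 CPM in libraries labelled mutant (SD, n = 3 each), a log2 fold change of 0.29 ± 0.06 (SE), with an adjusted p = 0.0276 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. An exact two-sided permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow. The postmitotic call was lost when any 1 library other than mutant 1 was left out, with adjusted p up to 0.184 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, while the log2 fold change stayed between 0.27 and 0.32. Counts were summed over the whole gene, so transcripts that lack only the floxed part still count, and the antisense genes Gm27197 and Gm13584 overlap it. Because the targeted gene does not show the deletion, groups are named below by their labels alone. Neurod6, which was looked up after the values were seen because NexCre sits in its locus, fell by 0.61 ± 0.11 on the log2 scale in the postmitotic libraries labelled mutant (adjusted p = 0.0135, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). That call was lost without postmitotic control 1 or control 2, with adjusted p up to 0.08 in the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

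**Figure D1:**
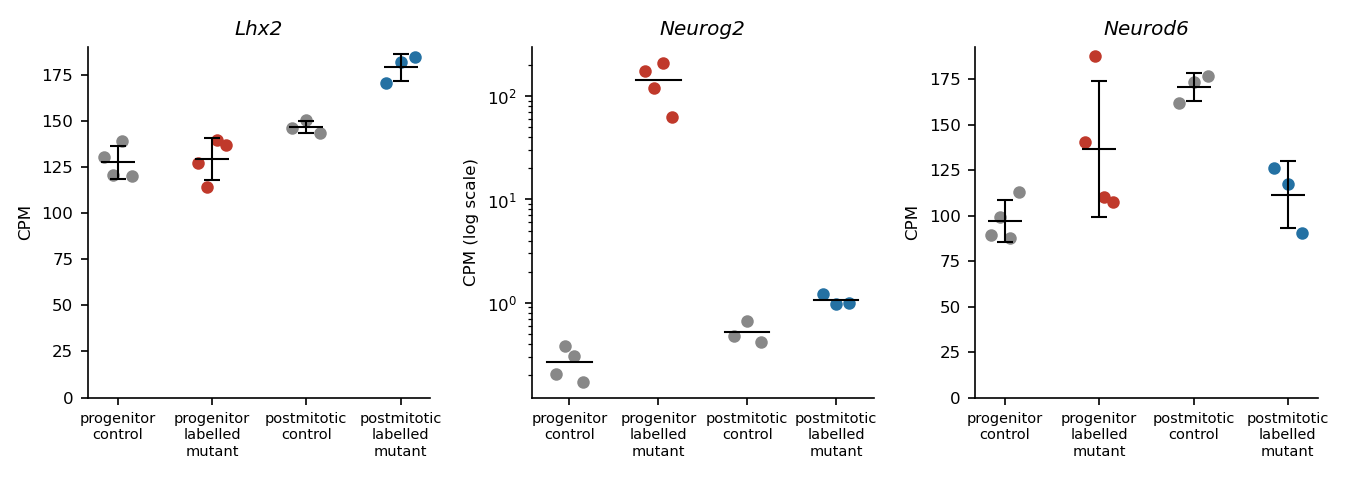
CPM of Lhx2, Neurog2 and Neurod6 in each library, grouped by experiment and label, with the group mean as a horizontal bar and, for Lhx2 and Neurod6, the SD as an error bar; the Neurog2 axis is logarithmic and carries no error bar. Lhx2 lies between 114 and 140 CPM in every progenitor library, and Neurog2 is at or below 1.21 CPM in all libraries except the progenitor libraries labelled mutant.

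The progenitor comparison asks which transcripts differ at postnatal day 5 after Cre was introduced into progenitors. The largest rise among called genes was that of Neurog2, a proneural factor that promotes neurogenesis in cortical progenitors. It stood at 0.265 ± 0.0955 CPM in controls and at 142 ± 64.5 CPM in libraries labelled mutant (SD, n = 4 each), with 5 to 10 counts per control library and 1466 to 5064 counts per library labelled mutant. Its log2 fold change was 9.05 ± 0.65 (SE), with an adjusted p = 0.000327 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Neurog2 lies on chromosome 3, 127633135 to 127635631, plus strand (GRCm38/mm10), and no annotated gene overlaps it. Nr4a2, a nuclear receptor of deep cortical and subplate neurons, fell by 2.07 ± 0.50 on the log2 scale, and Cplx3, a complexin of subplate neurons, fell by 1.80 ± 0.45.

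Among the genes that met the limits for naming, those with the next largest rises included Prss56, a serine protease (4.52 ± 0.30, log2 ± SE), Fst, which encodes the activin antagonist follistatin (2.59 ± 0.28), Aldh1a3, a retinoic acid synthesis enzyme (2.51 ± 0.60), Clec3b (2.29 ± 0.23), Nt5dc3 (2.28 ± 0.19) and Tdrd1 (2.12 ± 0.30). Zfp33b (3.76 ± 0.33), H2-T24 (3.07 ± 0.26) and Dnah7b (2.15 ± 0.32) also rose, but each belongs to a family of similar genes whose reads the counting could have divided. Among the large falls were those of Samd11 (-2.11 ± 0.19), Zfp605 (-1.87 ± 0.07), Cryab, a small heat shock protein (-1.69 ± 0.27), Cartpt, a neuropeptide precursor (-1.64 ± 0.20), and Fbxo2 (-1.57 ± 0.12). Erdr1 (-3.47 ± 0.59) and Rsph3b (-1.77 ± 0.44) also fell, and near-identical copies may share their reads. Genes on the opposite strand overlap H2-T24, Fst, Samd11 (Noc2l), Zfp605, Rsph3b and Cryab (Hspb2), and the strand setting of the counting is not given in the sources used here. Among genes fixed in advance, Sox11, a factor of young neurons, rose by 0.62 ± 0.07. Cux1 (-0.09 ± 0.13), Cux2 (0.16 ± 0.13), Axin2 (0.05 ± 0.09) and Lef1 (0.09 ± 0.17) did not pass the test. Leaving out 1 library ended the calls of Aldh1a3 (controls 1, 2 or 4), Nr4a2 (each library except control 1 and mutant 4), Cplx3 (controls 2 or 4, mutants 1, 2 or 3) and Rsph3b (controls 2 or 4, mutants 2 or 3), with adjusted p up to 0.0697, 0.0758, 0.0709 and 0.0639 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

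**Figure D2:**
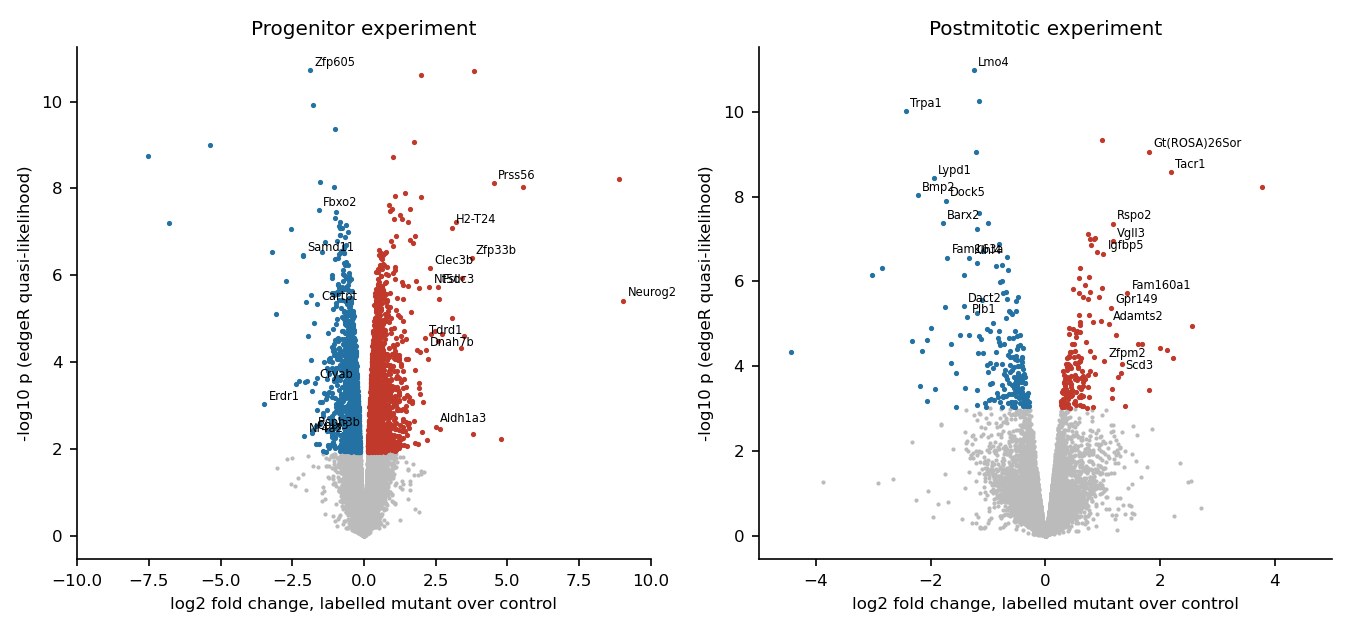
Each tested gene by its log2 fold change, libraries labelled mutant over control, and the negative log10 of its unadjusted p in edgeR's quasi-likelihood test, for the progenitor (left) and postmitotic (right) experiments. Red and blue points are the 3577 and 348 called genes, higher and lower in libraries labelled mutant, grey points are the others, and labels mark genes named for large changes.

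Genes of the excitatory synapse were lower at the median in the progenitor libraries labelled mutant. Of 64 measured members, 20 fell and 3 rose (21 and 5 adjusted over the list alone), among them Cacng3, an AMPA receptor auxiliary subunit (-1.02 ± 0.08), Lrrtm3, a synaptic adhesion protein (-0.88 ± 0.07), and Syn2, a synaptic vesicle protein (-0.67 ± 0.08). The median log2 fold change was -0.09 and camera with a preset correlation gave adjusted p = 0.00406, but adjusted p = 0.946 with an estimated correlation. Of 77 nuclear genes of oxidative phosphorylation, 19 fell and 0 rose (28 and 0 adjusted over the list alone), such as Sdhd (-0.38 ± 0.06) and Atp5a1 (-0.25 ± 0.05), with a median of -0.15. Camera gave adjusted p = 5.05e-07, against adjusted p = 0.946 with an estimated correlation. Of 24 cholesterol synthesis genes, 5 fell and 0 rose (also 5 and 0 adjusted over the list alone), such as Stard4 (-0.42 ± 0.05) and Insig1 (-0.32 ± 0.06). Camera gave adjusted p = 0.0132 and adjusted p = 0.946 with an estimated correlation. Cell cycle genes were higher, with 13 of 41 risen and 0 fallen (14 and 0 adjusted over the list alone), such as Top2a (0.60 ± 0.12) and Cenpf (0.52 ± 0.10). Their median was 0.30 and camera adjusted p = 7.27e-06, against adjusted p = 0.946 with an estimated correlation. Microglia and macrophage markers were lower, with 2 of 24 fallen (0 adjusted over the list alone), Ctss (-0.40 ± 0.13) and Aif1. Their median was -0.37 and camera adjusted p = 0.00469, against adjusted p = 0.946 with an estimated correlation. Without progenitor mutant 4 the cholesterol list had adjusted p = 0.057, and without progenitor control 3 the microglia list had adjusted p = 0.0556, both with the preset correlation. These libraries can be split into equal groups in 35 ways, the real one included. Of these, 4 moved the synapse median as far from 0 (highest other 0.115) and 2 that of oxidative phosphorylation. Cholesterol synthesis and microglia had 3 each, and cell cycle genes 1, the real split. The calls of Ctss and Aif1 were lost without any 1 of 6 libraries, with adjusted p up to 0.085 and 0.1 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

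The other lists did not pass camera in the progenitor experiment, although single members were called. Over all 15295 tested genes, 1838 were called higher and 1739 lower (23.4%). Called members alone therefore do not set a list apart. Upper-layer identity genes went both ways, with 7 of 32 risen and 10 fallen (7 and 13 adjusted over the list alone). Inhba, an activin subunit, rose by 1.07 ± 0.11 and Calb1, a calcium buffer, fell by 1.03 ± 0.12. Of 35 deep-layer genes 4 fell and 0 rose (1 and 0 adjusted over the list alone), with a median of -0.18. Of 102 genes of dendrite growth and branching, 15 rose and 13 fell (17 and 13 adjusted over the list alone), including Camk2a, a synaptic kinase (-0.81 ± 0.08), and Celsr3, an atypical cadherin (0.55 ± 0.07). Of 52 Wnt ligands, receptors and regulators 6 rose and 6 fell (the same numbers adjusted over the list alone), including Wnt9a (-1.54 ± 0.10) and Rspo3 (-0.86 ± 0.15). Of 22 Wnt/beta-catenin target genes 2 rose and 1 fell (2 and 0 adjusted over the list alone), with Myc at 0.50 ± 0.06. Of 34 proneural and differentiation factors 7 rose and 4 fell (11 and 5 adjusted over the list alone), including Nfix (0.46 ± 0.05) and Neurod1 (-0.65 ± 0.08). Of 72 axon guidance genes 15 rose and 3 fell, of 39 cadherins and protocadherins 5 rose and 1 fell, and of 28 immature neuron genes 7 rose and 1 fell, in each case with the same numbers adjusted over the list alone. Of 65 voltage-gated channels 8 rose and 19 fell (9 and 22 adjusted over the list alone), and of 30 Notch pathway genes 7 rose and 3 fell (8 and 5). Of 30 heat shock and unfolded protein response genes 1 rose and 8 fell (1 and 9 adjusted over the list alone), and of 27 p53 targets 3 rose and 5 fell (3 and 6), with Cdkn1a, a cell cycle inhibitor, at -1.12 ± 0.12. Among markers of other cell types, 6 of 26 astrocyte markers fell, such as S100b (-0.82 ± 0.17), and 3 of 27 endothelial and mural markers rose, such as Abcc9 (0.70 ± 0.12), with the same numbers adjusted over the list alone. Camera with a preset correlation gave adjusted p = 0.0951 and 0.0606 for these lists.

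At an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3577 of 15295 tested genes differed (23.4%), 1838 higher and 1739 lower, with a median absolute log2 fold change of 0.35. Of them 299 changed by more than 2-fold, 182 up and 117 down. The authors' deposited table for this experiment called 3977 genes, of which 3500 were also called here, all with the same sign. Without progenitor mutant 3 the count was 2383. With Y-linked CPM as a covariate, an alternative chosen after seeing the data, it was 948, and 39 of 105 calls of named genes ended.

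The postmitotic comparison asks which transcripts differ when Cre acts only after the last division. Among genes that met the limits for naming, the largest falls included Trpa1, a cation channel (-2.43 ± 0.14, log2 ± SE, n = 3 per group), Bmp2, a bone morphogenetic protein (-2.23 ± 0.18), Lypd1, a modulator of nicotinic receptors (-1.94 ± 0.14), Barx2, a homeobox factor (-1.79 ± 0.16), and Dock5 (-1.74 ± 0.14). Lmo4, a LIM-only protein of upper-layer neurons, fell from 223 ± 2.93 CPM to 94.1 ± 1.98 CPM (SD, n = 3 each) with the smallest p of all genes (log2 fold change -1.25 ± 0.06, adjusted p = 1.88e-07, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The largest rises under the same limits were those of Tacr1, the substance P receptor (2.19 ± 0.16), the noncoding Gt(ROSA)26Sor (1.82 ± 0.12), Fam160a1 (1.43 ± 0.18), Scd3, a fatty acid desaturase (1.32 ± 0.24), Vgll3 (1.18 ± 0.12) and Rspo2, a Wnt agonist (1.18 ± 0.11). Gt(ROSA)26Sor lies opposite Thumpd3 and Lypd1 opposite Gpr39, so their reads cannot be told apart where the counting ignored strand.

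Gpr149 (1.14 ± 0.15), Adamts2 (1.10 ± 0.16), Zfpm2, a cofactor of GATA proteins (1.03 ± 0.17), and Igfbp5 (1.01 ± 0.10) rose as well. Fam163a (-1.71 ± 0.18), Dact2 (-1.42 ± 0.17), Plb1 (-1.36 ± 0.19) and Klhl4 (-1.32 ± 0.14) fell. Among the genes fixed in advance, Cux1, an upper-layer factor, fell by 0.47 ± 0.06 and Sox11 rose by 0.28 ± 0.06. Neurog2 (1.01 ± 0.31), Cux2 (0.17 ± 0.07), Axin2 (0.07 ± 0.09) and Lef1 (-0.15 ± 0.25) did not pass the test. The call of Sox11 was lost without any 1 of the 6 libraries, and those of Scd3 and Zfpm2 without postmitotic control 1 or 2, with adjusted p up to 0.189, 0.0937 and 0.0665 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

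Deep-layer identity genes were higher and upper-layer genes lower at the median in the postmitotic libraries labelled mutant. Of 35 measured deep-layer genes 10 rose and 0 fell (17 and 3 adjusted over the list alone), including Thsd7b (0.99 ± 0.12), Ldb2, a LIM-domain cofactor (0.91 ± 0.09), and Tbr1, a factor of layer VI neurons (0.49 ± 0.07). The median log2 fold change was 0.34 and camera with a preset correlation gave adjusted p = 2.48e-07, but adjusted p = 0.789 with an estimated correlation. Of 33 upper-layer genes 7 fell and 1 rose (13 and 7 adjusted over the list alone), including Cadps2, a vesicle priming protein (-1.20 ± 0.08), Lmo4 and Cux1, while Cdh13 rose by 0.59 ± 0.07. The median was -0.11 and camera gave adjusted p = 0.027, against adjusted p = 0.789 with an estimated correlation. That call was also lost without postmitotic control 1, control 3 or mutant 1, with adjusted p up to 0.116 under the preset correlation. Of the 10 ways to split these libraries into equal groups, the real one included, 2 moved the upper-layer median as far from 0 (highest other 0.125). For the deep-layer median only the real split did so, with 0.318 as the highest other.

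Of 72 axon guidance genes 9 rose and 5 fell (18 and 8 adjusted over the list alone), with Epha7, an ephrin receptor, at 0.75 ± 0.07 and Efna5, an ephrin, at -0.87 ± 0.10. Camera gave adjusted p = 0.0143, against adjusted p = 0.789 with an estimated correlation. Of 38 cadherins and protocadherins 5 rose and 1 fell (9 and 3 adjusted over the list alone), with Fat1 at 0.80 ± 0.08. Camera gave adjusted p = 0.0118, against adjusted p = 0.818 with an estimated correlation. Both calls were lost without postmitotic mutant 2 or mutant 3, with adjusted p up to 0.0858 and 0.092. Of 28 immature neuron genes 3 rose and 0 fell (6 and 0 adjusted over the list alone), with Islr2 at 0.84 ± 0.08. Their median was 0.12 and camera adjusted p = 3.91e-05, against adjusted p = 0.789 with an estimated correlation. Of 50 Wnt ligands, receptors and regulators 3 rose and 3 fell, with Frzb, a secreted Wnt antagonist, at -1.34 ± 0.21, and of 21 Wnt/beta-catenin target genes 1 rose and 0 fell, in both cases also when adjusted over the list alone. Of 102 genes of dendrite growth and branching 3 rose and 5 fell (6 and 7 adjusted over the list alone), including Nrp1, a semaphorin receptor (0.52 ± 0.09), Ptn (-0.39 ± 0.06) and Camk2a (-0.50 ± 0.08). Of 13 LIM-homeodomain factors and cofactors 1 rose and 2 fell (4 and 3 adjusted over the list alone), the falls being Lmo4 and Lmo3 (-1.01 ± 0.09). Of 64 excitatory synapse genes 0 rose and 3 fell (0 and 5 adjusted over the list alone), led by Slc17a6, a vesicular glutamate transporter (-1.08 ± 0.11), and of 64 voltage-gated channels 1 rose and 4 fell (4 and 10).

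Of the lists of other cell types and cycling cells, 5 passed camera toward lower values with a preset correlation. The medians were -0.20 for 25 astrocyte markers, -0.19 for 21 oligodendrocyte lineage markers, -0.12 for 25 endothelial and mural markers, -0.12 for 26 radial glia and progenitor markers and -0.18 for 41 cell cycle genes. Of these lists, radial glia had 1 member fallen, Emx1 (-0.80 ± 0.08; 1 risen and 4 fallen adjusted over the list alone), and the cell cycle list had 1 risen, Mcm6 (0.45 ± 0.09; also 1 adjusted over the list alone), against the sign of its median. The other 3 had 0 called members (5 astrocyte markers fallen adjusted over the list alone, 0 in the others). Camera with a preset correlation gave adjusted p = 1.3e-05, 0.0136, 0.0276, 0.027 and 0.0175 in that order, and adjusted p = 0.789, 0.789, 0.862, 0.789 and 0.862 with an estimated correlation. With 1 library left out and the preset correlation, the last 4 lists lost their calls, with adjusted p up to 0.115 (oligodendrocyte, without control 2 or mutant 2), 0.375 (endothelial, without control 2, mutant 1 or mutant 3), 0.314 (radial glia, without control 2, control 3 or mutant 1) and 0.241 (cell cycle, without control 2, mutant 1 or mutant 2). The call of Mcm6 was lost without any library but mutant 3 (adjusted p up to 0.131, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Heat shock and unfolded protein response genes had 0 of 30 members called, a median of -0.15 and camera adjusted p = 0.0143, against adjusted p = 0.789 with an estimated correlation and 0.115 at most without control 3 or mutant 2.

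**Figure D3:**
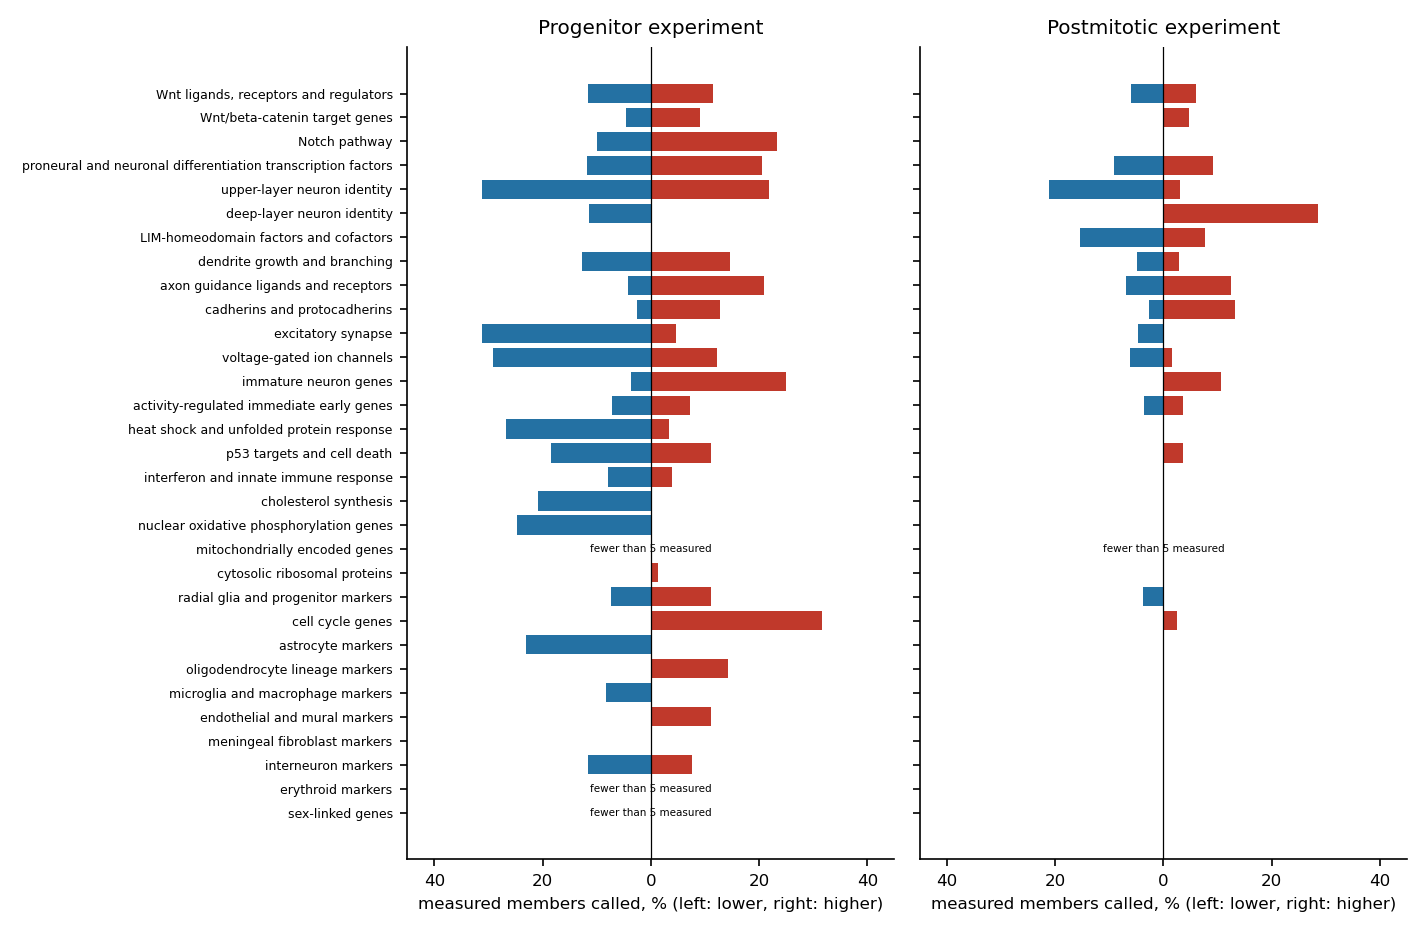
Share of the measured members of each fixed list that were called lower (left of 0) or higher (right of 0) in libraries labelled mutant, in percent, for the progenitor and postmitotic experiments. Cell cycle genes have 13 of 41 members called higher in the progenitor experiment and 1 of 41 in the postmitotic one. Over all tested genes, 1838 of 15295 and 159 of 17775 were called higher, so shares are not comparable between the experiments.

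At an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 348 of 17775 tested genes differed (1.96%), 159 higher and 189 lower. Of them 72 changed by more than 2-fold, 24 up and 48 down. The authors' deposited table for this experiment, whose mean counts are those of libraries 1 and 2 of each group alone, called 360 genes, of which 214 were also called here, all with the same sign. From those 4 libraries alone 314 genes were called here, 268 of them also in the authors' deposited table. The count was 160 without postmitotic control 2 and 197 without control 3, and it was 723 when no filter on low counts was applied.

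The contrasts of labelled mutant against control were also tested for their difference between the 2 experiments. Gipr, the receptor of a gut incretin hormone, differed by 1.70 ± 0.11 on the log2 scale (progenitor minus postmitotic, SE; adjusted p = 4.46e-07, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with 14.5 ± 0.514 CPM in progenitor controls and 57.9 ± 6.65 CPM in progenitor libraries labelled mutant (SD, n = 4 each). Satb1, a chromatin organiser, fell in the postmitotic experiment (-1.16 ± 0.06) and had a value of -0.10 ± 0.08 in the progenitor one, a difference of 1.05 ± 0.11. Lmo3 differed by 1.06 ± 0.11 and Trpa1 by 2.10 ± 0.22, both having fallen in the postmitotic experiment. Tacr1 (-2.18 ± 0.22) and Gt(ROSA)26Sor (-1.62 ± 0.17) had risen there. Wnt9a (-1.71 ± 0.16) and Aacs, an acetoacetate-activating enzyme (-0.96 ± 0.09), had fallen in the progenitor experiment. Gm2897 differed by 1.81 ± 0.16, and Gm5801 had 4.36 to 7.25 CPM in progenitor controls and 0.0830 to 0.216 CPM (2 to 5 counts) in progenitor libraries labelled mutant, against 1.55 to 2.05 CPM and 1.81 to 3.66 CPM in the postmitotic groups. Both carry predicted-gene names, and similar copies may share their reads. Neurog2 differed by 8.04 ± 1.48, a call that was lost without postmitotic control 2 (adjusted p = 0.0527, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The effects on Lhx2 did not pass the test of their difference (-0.26 ± 0.10, adjusted p = 0.106 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). In all, 1086 of 15643 genes differed, 601 with a higher and 485 with a lower value in the progenitor experiment. The count was 598 without postmitotic control 1, 637 without postmitotic mutant 1, 698 without progenitor control 4, 714 without postmitotic control 2 and 718 without progenitor mutant 3. With DESeq2 it was 1640, with 804 higher and 836 lower. The experiment is confounded with the tables, their annotation and any difference in handling, so only the contrasts of labelled mutant against control were compared. The contrasts also differ in the source of Cre, a plasmid or an allele at the Neurod6 locus, and in the cells that receive it. Timing cannot be told apart from these.

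Genes called in both experiments went the same way more often than independent lists would. Among 14449 genes tested in both, 51 rose in both, where 18.2 are expected of independent lists (odds ratio 3.83, two-sided Fisher's exact test, p = 1.94e-12, Benjamini-Hochberg adjusted over both directions 1.94e-12), and 67 fell in both, where 20.6 are expected (odds ratio 4.81, p = 9.42e-20, adjusted 1.88e-19 in the same Fisher's exact test). Another 14 genes were called in opposite directions, and genes are not independent replicates. The 118 genes that went the same way became 51 without postmitotic control 2, 62 without postmitotic control 3 and 66 without postmitotic mutant 2. They were 188 with DESeq2 and 195 without a filter on low counts. Those that rose in both, in the order progenitor and postmitotic, included Mn1 (0.64 ± 0.08 and 0.78 ± 0.08), Adgrl2, a latrophilin (0.77 ± 0.09 and 0.49 ± 0.06), Ttc28 (0.87 ± 0.07 and 0.61 ± 0.09), Vgll3 (1.33 ± 0.20 and 1.18 ± 0.12) and Ptprk, a receptor phosphatase (0.51 ± 0.06 and 0.41 ± 0.07). Those that fell in both included Ddn, dendrin, a postsynaptic protein (-0.71 ± 0.07 and -0.51 ± 0.07), Camk2a (-0.81 ± 0.08 and -0.50 ± 0.08), Lrrtm3 (-0.88 ± 0.07 and -0.64 ± 0.10), Chrm1, a muscarinic receptor (-0.54 ± 0.06 and -0.49 ± 0.08), and Dact2, a Wnt pathway modulator (-1.09 ± 0.16 and -1.42 ± 0.17). The call of Ptprk in the postmitotic experiment was lost without control 2 (adjusted p = 0.055, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Across all 14449 genes the log2 fold changes of the experiments had a Pearson r of 0.09 and a Spearman rho of 0.11, with 53.2% of signs alike. Across the 3476 of them called in the progenitor experiment these were 0.21, 0.22 and 58.9%, and across the 323 called in the postmitotic experiment 0.31, 0.40 and 71.5%.

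**Figure D4:**
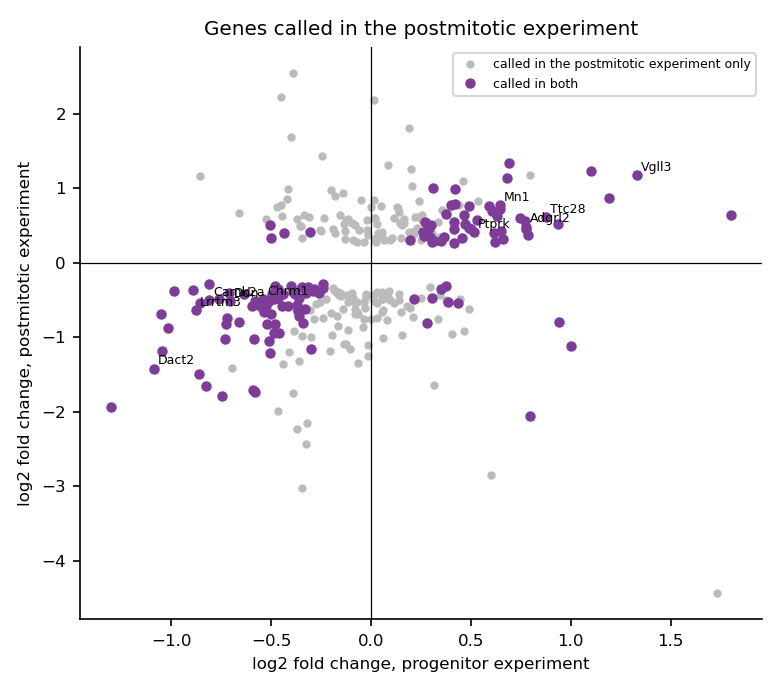
Log2 fold change, libraries labelled mutant over control, in the progenitor (horizontal) and postmitotic (vertical) experiments of the 323 genes called in the postmitotic experiment and tested in both, with genes called in both in purple. Of the purple points, 67 lie at the lower left, 51 at the upper right and 14 in the other corners.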

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

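The tests of Neurog2 and Lhx2, and those of neighbouring genes and of spread within postmitotic groups, were chosen only after the result was seen; those of sex, depth, exon length and other splits were fixed before their results were seen.

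Neurog2 differed by 8.04 on the log2 scale between the contrasts of the 2 experiments, and stood at 63.4 to 210 CPM in the progenitor libraries labelled mutant. Intermediate progenitor cells carried into those libraries are argued against: the median log2 fold change of 8 tested genes of such cells, from a list of 12 of which 11 are also in the fixed lists, was 0.14, and their highest upper 95% bound was 2.32, against a lower bound of 7.50 for Neurog2. A Neurog2 sequence carried by the Cre plasmid cannot be told apart from a rise of the cells' own gene after the deletion: both predict counts in these 4 libraries alone. The second also predicts a rise of genes known to follow Neurog2, which was not tested, as no list of them was fixed; of some looked up after the values were seen, Insm1 (0.61 ± 0.15), Neurod2 (0.30 ± 0.06) and Hes6 (0.24 ± 0.06) rose, Neurod1 (-0.65 ± 0.08) and Rnd2 (-0.24 ± 0.07) fell, and Neurod6 (0.49 ± 0.18), Dll1 (0.14 ± 0.11) and Gadd45g (-0.03 ± 0.16) did not pass the test. The highest value elsewhere was 1.21 CPM among the 10 libraries without the Cre plasmid and 0.381 CPM among progenitor controls, and read positions, which could decide, were not analysed here.

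The number of genes changed in the progenitor experiment, 3577, exceeded that of every other of the 35 splits of its libraries (highest 3). That is the smallest share that 35 splits allow, and it argues against chance alone for the count. Other splits mix the groups, so any difference between the groups as wholes, such as sex or depth, could give this too. Only 5 autosomal genes were called for sex in the postmitotic libraries, against 3406 here, which argues against sex as the whole cause of large changes. That fit had 3 libraries of each sex and can miss changes as small as the median absolute log2 fold change here (0.35). In it 1214 autosomal genes had an unadjusted p under 0.05 in edgeR's quasi-likelihood test. With Y-linked CPM as a covariate 948 genes were called in the progenitor experiment. That covariate runs with the label, and the SE of Lhx2, for example, widened from 0.0716 to 0.119. A trend on exon length is argued against by the 3757 genes called after its removal. The higher depth of every control is argued against by the 3539 called with all libraries thinned to the lowest total. Among 283 genes changed over 2-fold, 68 neighbouring pairs lay within 1 Mb, against 48 to 88 in the middle 95% of random draws. Pairs whose symbols share their first 3 letters were left out, so many clustered gene families were not counted. The pair count argues against a general excess of neighbours but cannot exclude a few inherited blocks. In 1 window on chromosome 3, all 3 tested genes (S100a3, S100a4 and S100a6) had fallen over 2-fold. Of 227 genes changed over 2-fold, 12 had a log2 range over 2 within a postmitotic group, against 2.76 in matched draws. A spread inherited between animals predicts this, for those genes only. Small effects of sex, a few inherited blocks, a difference in strain spread over the genome and the deletion itself stay open.

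Lhx2 was not lower in either set of libraries labelled mutant. Swapped postmitotic labels are argued against by Neurod6, whose locus holds Cre in NexCre, at -0.61 in the libraries labelled mutant. RNA of cells that kept the gene cannot be told apart from a missing deletion in the progenitor experiment, where the 95% interval allows a fall of at most 8.86%, because the share of deleted cells was not analysed here. Reads from outside the floxed part could keep the gene count up, and the postmitotic fold of 1.22 decides nothing, because exon counts were not analysed here.

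For the other counts, the 1086 genes whose change differed between the experiments exceeded every other split drawn (highest 771, 100 splits drawn). These splits also break up the groups within each experiment, so they test for no effect at all. They cannot tell a difference between the effects from chance. For the 118 shared genes the same splits (highest other 0) decide nothing, because other splits within an experiment called at most 12 genes. Chance cannot be excluded for the 5 lists that moved in the progenitor experiment, since 32 of 35 splits gave as many and the highest gave 18. The 10 splits of the postmitotic libraries are too few for a share under 0.05; they gave 348 genes for the real split and 12 at most for another, and 11 lists for the real split, with 4 splits as high and 12 at most for another.

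A direct test found differences between the contrasts of the experiments (log2, progenitor minus postmitotic) for these other named genes. Higher in the progenitor experiment were Prss56 (4.77), H2-T24 (3.12), Fst (2.52), Nt5dc3 (2.12), Trpa1 (2.10), Bmp2 (1.85), Gm2897 (1.81), Clec3b (1.76), Tdrd1 (1.72), Gipr (1.70), Dnah7b (1.67), Lmo4 (1.23), Dock5 (1.16), Fam163a (1.11), Lmo3 (1.06), Satb1 (1.05), Barx2 (1.04), Klhl4 (0.96) and Sox11 (0.34). Lower were Cplx3 (-2.95), Samd11 (-2.70), Tacr1 (-2.18), Zfp605 (-2.08), Cryab (-1.80), Wnt9a (-1.71), Cartpt (-1.68), Fam160a1 (-1.68), Gt(ROSA)26Sor (-1.62), Fbxo2 (-1.30), Scd3 (-1.24), Aacs (-0.96) and Igfbp5 (-0.70). The fitted value of Gm5801 (-5.92) rests on 2 to 5 counts per progenitor library labelled mutant and depends on the prior count. That of Prss56 rests on 1 to 8 counts per postmitotic control and 3 to 5 per postmitotic library labelled mutant, and Prss56 was not tested in that experiment alone. Barx2, Dock5 and Fam163a were called lower in both experiments, and Sox11 and Igfbp5 higher, so they differ in the size of the change. The call of Sox11 was lost in 10 of the fits that left out 1 library, all but those without progenitor control 3, progenitor mutant 3 or 4, or postmitotic control 2 (adjusted p up to 0.105, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). That of Neurog2 was lost without postmitotic control 2 (adjusted p = 0.0527 in the same edgeR test). Lists differed for cell cycle (camera adjusted p = 2.98e-06), deep-layer identity (3.65e-05), nuclear oxidative phosphorylation (0.00103), endothelial and mural markers (0.00772), excitatory synapse (0.0386) and microglia (0.0386), all with adjusted p = 0.929 with an estimated correlation.

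Single libraries stood apart from the other 3 of their group in 3 of 76 groups tested, where chance gives 5%: progenitor control 3 for Sox11 (212.9 CPM, others 179.6 to 183.1) and Lef1 (7.82 CPM, others 5.90 to 6.22), and progenitor control 1 for Mn1 (75.7 CPM, others 87.2 to 88.6).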

How the results depend on the processing

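No named gene or list changed direction where it was called in either of the fits compared. Lhx2 in the progenitor experiment, not called, lay between -0.0152 and 0.0798 with 1 library left out. The larger side of the calls did turn: progenitor calls were 1952 higher and 2048 lower with DESeq2 and 1741 and 2016 after removal of the exon length trend, postmitotic calls 156 and 138 without mutant 1 and 362 and 361 without the filter on low counts, and the difference 804 and 836 with DESeq2. The alternatives with Y-linked CPM, X and Y genes, pseudogenes, exon length, thinned counts, postmitotic libraries 1 and 2 alone, the difference of lists or shared genes with 1 library left out were chosen after seeing the data, and where a call ended the cause was not tested beyond fewer libraries or genes.

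Tested against a fold of 1.5, the counts of called genes were 95 (progenitor), 32 (postmitotic) and 50 (difference). With Y-linked CPM as a covariate the progenitor count was 948, and without a filter on low counts the postmitotic count was 723. The difference count was 1640 with DESeq2, 2017 as a z of the separate fits and 1938 at an adjusted p under 0.1. The 118 shared genes became 187 at an adjusted p under 0.1, 188 with DESeq2 and 195 without the filter. With an estimated correlation 0 lists were called in either experiment or for the difference, and with fry 1 (progenitor) and 0 (postmitotic). The list called by fry, proneural and differentiation factors, was not among the 5 that passed camera in the progenitor experiment.

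With 1 library left out, progenitor calls ranged from 2383 (without mutant 3) to 3712, and postmitotic calls from 160 (without control 2; 197 without control 3) to 467. The difference count ranged from 598 (without postmitotic control 1) to 1481, with 637 without postmitotic mutant 1, 698 without progenitor control 4, 714 without postmitotic control 2 and 718 without progenitor mutant 3. Shared genes ranged from 51 (without postmitotic control 2; 62 without control 3 and 66 without mutant 2) to 142. Lists ranged from 5 to 8 (without progenitor control 1) and from 6 (without postmitotic mutant 2) to 11. Lhx2 in the postmitotic experiment ranged from 0.265 to 0.322 and lost its call without control 1, 2 or 3 or mutant 2 or 3, in 1 fit of all 14 libraries (0.289, adjusted p = 0.0555 in edgeR) and from libraries 1 and 2 of each group alone (0.252, adjusted p = 0.226 in edgeR). Leaving out some library ended the calls of 15 of 105 named progenitor genes, 15 of 62 postmitotic and 2 of 12 for the difference. The Y-linked covariate ended 39 of the 105, and 1 fit of all 14 libraries 16 of the 62.

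Same-numbered libraries did not deviate together (correlations -0.436 to 0.0931 in the progenitor and -0.196 to 0.0256 in the postmitotic experiment), and only progenitor number 4 correlated best with its own number. With the replicate number as a block (replicate block), Lhx2 in the postmitotic experiment was 0.287 (adjusted p = 0.114 in edgeR), the difference count 659, the shared count 66, the progenitor count 3073 and the postmitotic count 246. At the depth, spread and number of libraries here, whose parts were not separated, simulated 1.5-fold changes were called for 62.7% of progenitor and 49.3% of postmitotic genes. The simulation changed far fewer genes than the 3577 called in the progenitor experiment. The adjusted threshold depends on that number, so these shares need not hold for the real fits.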

Other observations

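The test of chromosome 6 was chosen only after the result was seen; that of maturation was written before, but its verdict was made stricter, by asking also for the other splits, after its list tests had been seen.

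Further lists in the progenitor experiment did not pass camera. Of 27 radial glia and progenitor markers 3 rose and 2 fell (2 and 0 adjusted over the list alone), of 21 oligodendrocyte lineage markers 3 rose and 0 fell, of 26 interneuron markers 2 rose and 3 fell, of 25 interferon and innate immune genes 1 rose and 2 fell, and of 75 cytosolic ribosomal proteins 1 rose and 0 fell, with the same numbers adjusted over the list alone unless given. Of 28 activity-regulated immediate early genes 2 rose and 2 fell (2 and 1 adjusted over the list alone). Medians were -0.01 for 12 LIM-homeodomain factors and -0.12 for 19 meningeal fibroblast markers, with 0 called members. Erythroid markers (3 measured, 1 risen), sex-linked genes (1 measured) and mitochondrially encoded genes (0 measured) were too few to test.

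In the postmitotic experiment 33 proneural and differentiation factors had 3 risen and 3 fallen (7 and 6 adjusted over the list alone), and 28 activity-regulated immediate early genes had 1 and 1 (2 and 3). Of 27 p53 targets 1 rose and 0 fell. Lists with 0 called members had medians of -0.02 (30 Notch pathway genes), -0.14 (23 interferon and innate immune genes), -0.02 (24 cholesterol synthesis genes), -0.02 (82 nuclear oxidative phosphorylation genes), 0.01 (80 cytosolic ribosomal proteins), -0.08 (21 microglia and macrophage markers), 0.32 (15 meningeal fibroblast markers), 0.03 (26 interneuron markers, 1 fallen adjusted over the list alone), -0.06 (7 erythroid markers) and -1.12 (5 sex-linked genes). None of these lists passed camera, and mitochondrially encoded genes (0 measured) were not tested.

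A candidate explanation of the lower synaptic transcripts is less advanced neuronal maturation in the progenitor libraries labelled mutant. Of 21 genes that rise with maturation 16 fell and 0 rose (median -0.45, camera adjusted p = 8.16e-10, adjusted p = 0.283 with an estimated correlation). Of 20 genes that fall with maturation 6 rose and 2 fell (median 0.09, camera adjusted p = 0.0483, adjusted p = 0.406 with an estimated correlation), and 11 of the 20 are also in the fixed lists. Splits of the libraries cannot tell an effect of the deletion from another difference between the groups. The difference of the medians was 0.54, farther from 0 than in any other of the 35 splits (highest 0.40), which argues against chance alone. In the postmitotic experiment it was 0.25 (highest other 0.09), 10 splits being too few for a share under 0.05; there 2 of the rising genes rose and 0 fell, against the sign of their median (-0.12, camera adjusted p = 0.188), and the falling genes had camera adjusted p = 0.00388 (adjusted p = 0.33 with an estimated correlation).

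Whether chromosome 6 sequence inherited with the NexCre allele is a source of postmitotic changes was not decided. Of 211 tested genes within 20 Mb of Neurod6, 7 were called, against 1 to 8 in the middle 95% of random draws, and on the whole chromosome 24 of 344 called genes with a position, against 10 to 25. Both counts lie in the upper part of their range, which leaves room for an excess of a few genes, and Tacr1 and Gt(ROSA)26Sor lie on this chromosome outside the 20 Mb. Called postmitotic genes changed over 2-fold nevertheless formed 17 neighbouring pairs within 1 Mb among 71 genes. The middle 95% of random draws gave 1 to 8 pairs, and 0 of 1000 draws gave as many. Inherited blocks on any chromosome predict such an excess, so they stay open as a source of these changes. Pairs with similar symbols were left out, but clusters of predicted genes can still count, and other causes of the excess were not tested.

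A830036E02Rik and AA388235, chosen after their values were seen, nearly switched between progenitor groups. A830036E02Rik, which lies opposite Krt12, had 8.51 to 16.2 CPM in controls and 0 to 0.131 CPM in libraries labelled mutant. AA388235 had 0 to 0.0407 CPM in controls and 4.96 to 10.9 CPM in libraries labelled mutant. Within the postmitotic controls A830036E02Rik ranged from 0.197 to 14.3 CPM.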
